A study of Mus musculus with 24 samples.

How the data were processed

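Poly(A) RNA of 24 samples of cultured mouse adipocytes was sequenced, per the labels. Cells of the stromal vascular fraction were induced for 2 days with 0.5 mmol/l IBMX, 0.1 mg/ml insulin and dexamethasone, then kept for 5 days with 1 µg/ml insulin and 10% serum, per the labels' protocols. The labels give the depot, the genotype, the siRNA and a replicate number from 1 to 3, and groups were formed from the first 3. Control mice carry floxed Senp2, per the labels. The strand setting of counting is not given in the sources used here, so genes that overlap on opposite strands are uncertain.

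Reads were trimmed with cutadapt 2.7, aligned to GRCm38 with TopHat2 2.1.1 and counted with HTSeq, and differential expression was computed with edgeR, per the submitters' processing notes. The deposited table held the count of reads per gene, as whole numbers from HTSeq, for 53465 genes and 5 counter lines. The authors' per-sample files held a signal per gene that equalled the counts divided by 1 constant per library, to within 8.09e-05 counts at a tolerance of 0.001, so they were not used further. The counter lines held 27.5% to 39.5% of the listed reads in 23 libraries and 95.9% in iWAT aKO siNS replicate 2, and stayed out of library sizes and tests. Listed reads per library ranged from 13935083 to 21580220. Symbols, positions and gene types were added from GENCODE M21, which named 53274 identifiers and left 191 unnamed, and 80 genes had a duplicated symbol.

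Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 on the 8 groups, which left 14785. Libraries were scaled by TMM, with factors from 0.985 to 1.04 in 23 libraries and 0.840 in iWAT aKO siNS replicate 2. A negative binomial model with 1 mean per group and no block was fitted to the 24 libraries (estimateDisp, glmQLFit with robust = TRUE), and 12 contrasts were tested with the quasi-likelihood F test. P-values were adjusted by the method of Benjamini and Hochberg over the tested genes of each contrast, with a threshold of 0.05. Standard errors are those of the fit. The sources name edgeR but give no model, so the model is a choice of the re-analysis.

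Before the data were examined, 35 gene lists were fixed, covering metabolism, fat cell identity, stress responses, cell division and other cell types that a stromal vascular culture could hold. The 34 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and a variance trend, and adjusted over the lists of a contrast. A list of epithelial markers had 1 tested member of 14 and was not tested. Camera with an estimated correlation and fry were run beside it. The groups, contrasts, model, alternatives and the rule for named genes were also set before the data were examined. By that rule the text may name, in each contrast, 19 fixed genes whatever their result. It may also name the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1, without predicted genes. For these, the libraries of the 2 groups must not overlap, which is not asked of interactions. Last, it may name the 4 members with the smallest p of each called list and the 4 most expressed members of an uncalled list that is discussed. Not all genes that the rule allows are given.

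Replicate numbers were checked for pairing through correlations, across 8270 genes with a mean count of at least 200, of deviations from group means. Pairs of libraries with the same number in eWAT and iWAT had r from 0.0803 to 0.742, over 0.1 in 10 of 11 pairs and in the 3 pairs of Cont siNS, without the shallow library. Same-numbered libraries of different genotype or siRNA had a mean r of -0.0649 and -0.0325, so these numbers were not taken as pairs. The labels do not say what the numbers stand for. Agreement between contrasts was computed only for pairs of contrasts with no library in common.

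The fit was tested on simulated counts with 14489 genes. In the eWAT genotype contrast with siNS it recovered 44 of 67 genes changed 1.5-fold, 49 of 67 2-fold and 63 of 66 4-fold. In iWAT it recovered 46, 54 and 56 of as many, and in the eWAT interaction 36, 44 and 59. False calls were 9 of 165, 8 of 164 and 9 of 166. The interaction calls also held 18 of 23 further changed genes, members of a list raised 1.5-fold in eWAT Cont siCEBPb. In 2 contrasts without change edgeR QL called 0 genes. Camera recovered that list, and called 1 other and 0 in a contrast without change. These rates need not hold for real counts, whose genes are not independent.

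Alternatives were DESeq2 size factors, no filter, a stricter filter of CPM at least 1 in 12 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample weights, the groups of a contrast alone, a replicate block, a threshold on the fold change and each library left out in turn. Added after the data were seen were a fit without iWAT aKO siNS replicate 2 for contrasts that do not hold it, a block across depots, and a fit of summed eWAT and iWAT libraries. Figures were drawn from the tables of results. Sequence reads, exon usage of Senp2 and proteins were not examined.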

Results

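RNA was sequenced from adipocytes that were differentiated in culture from stromal vascular cells of mouse white fat. Cells came from epididymal (eWAT) and inguinal (iWAT) fat of control (Cont) mice and of mice with an adipocyte knockout of Senp2 (aKO), a protease that removes SUMO from proteins. They were treated with siRNA against Cebpb (siCEBPb) or with siNS, an siRNA name that the labels do not explain. The 24 libraries formed 8 groups of 3. Nothing in the labels says whether the replicates of a group were separate cultures or animals, so p-values measure only the spread between these samples.

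Counts assigned to genes ranged from 8435494 to 15388744 in 23 libraries. The other library, iWAT aKO siNS replicate 2, had 603585 gene counts from 14848750 listed reads, and 93.3% of its reads were not aligned. In the other libraries 16.8% to 27.6% were not aligned. Gm42418, a predicted gene, held 8.90% of the gene counts of that library and 1.09% to 1.57% of those of the others. The library was kept, because no reason for its low count is given in the labels, and counts of changed genes are also given without it. Below, log2 fold changes are given ± SE from the edgeR quasi-likelihood (QL) fit, with n = 3 libraries per group. Genes said to have risen, fallen or changed passed an adjusted p of 0.05 in the edgeR QL test, and gene lists are called from camera.

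**Figure D1:**
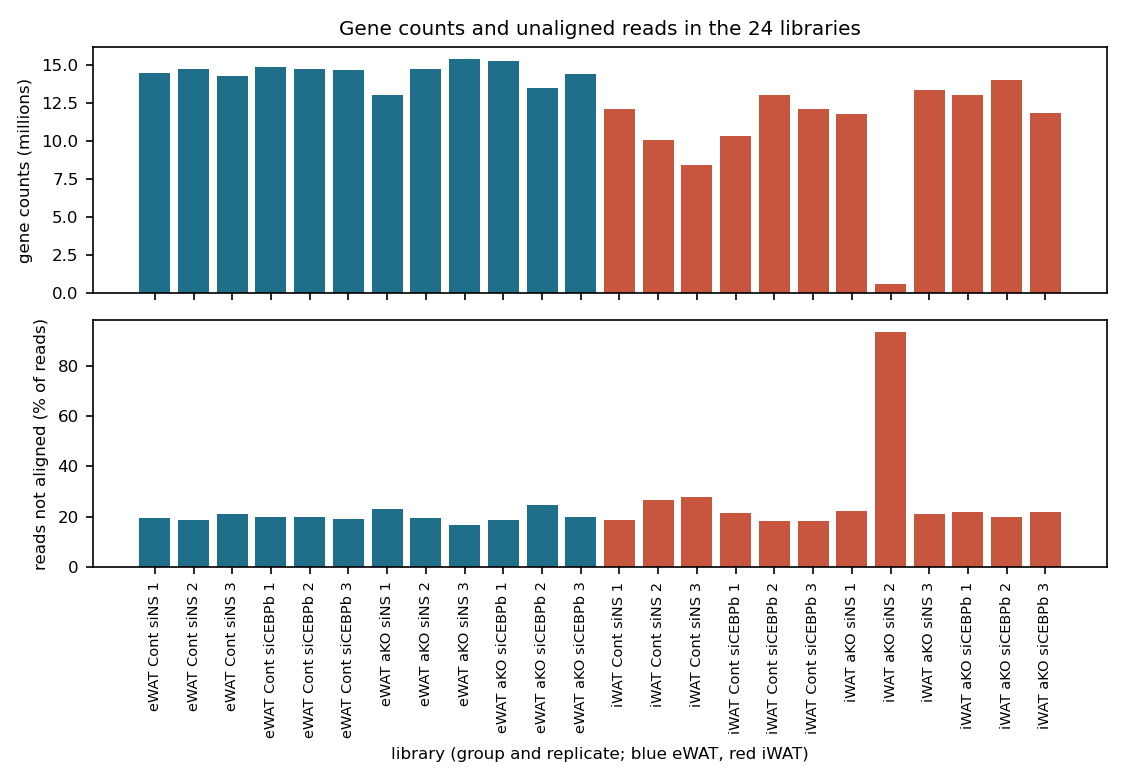
Gene counts (top) and the percentage of reads not aligned (bottom) in each of the 24 libraries, as bars, with eWAT in blue and iWAT in red. The library iWAT aKO siNS replicate 2 had 603585 gene counts and 93.3% of reads not aligned, against at least 8435494 and at most 27.6% in the others.

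The 2 targeted genes were examined first. Cebpb (ENSMUSG00000056501; GRCm38 chromosome 2, 167688915 to 167690418, plus strand) was measured at 168 ± 12.5 CPM (counts scaled by library size; mean ± SD, n = 3) in eWAT Cont siNS and at 50.4 ± 7.56 with siCEBPb. In eWAT aKO it was 151 ± 8.67 and 27.4 ± 6.49. The iWAT values were 125 ± 18.3 and 36.0 ± 2.02 in Cont, and 115 ± 11.9 and 18.5 ± 5.43 in aKO. Each siCEBPb library lay below each siNS library of its depot and genotype.

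Senp2 (ENSMUSG00000022855; chromosome 16, 22009484 to 22049269, plus strand) was measured at 54.5 ± 2.35 CPM in eWAT Cont siNS and 47.6 ± 4.82 in eWAT aKO siNS (log2 fold change -0.20 ± 0.072, edgeR QL adjusted p = 0.0519, 0.0322 without the shallow library). The value lay near the threshold, with an edgeR QL adjusted p of 0.00990 without eWAT aKO siNS replicate 1, 0.0490 with a replicate block, 0.0369 with DESeq2 size factors and 0.0440 with the stricter filter, and a voom adjusted p of 0.00233. In iWAT the values were 51.0 ± 4.67 and 51.5 ± 5.11 (-0.062 ± 0.082, edgeR QL adjusted p = 0.688). With siCEBPb, Cont and aKO were at 49.9 ± 0.910 and 53.2 ± 2.55 in eWAT and at 50.8 ± 2.7 and 53.2 ± 0.508 in iWAT. Gene counts include reads outside the deleted part and cells without Cre, so the Senp2 level checks nothing about the genotype labels. In iWAT aKO siNS replicate 2 the Senp2 value rested on 29 counts.

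**Figure D2:**
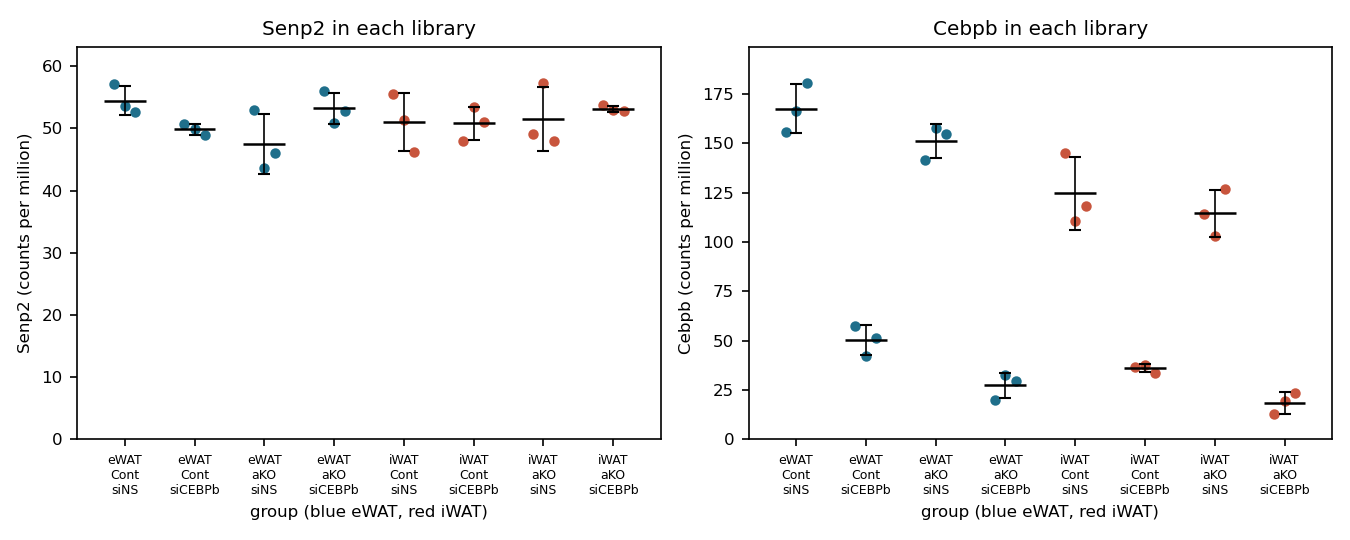
CPM of Senp2 (left) and Cebpb (right) in each library by group, with eWAT in blue and iWAT in red, a line at the mean of 3 libraries and bars of 1 SD. Cebpb was at 168 in eWAT Cont siNS and 27.4 in eWAT aKO siCEBPb, while Senp2 group means lay between 47.6 and 54.5.

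The first question was which genes differed between aKO and Cont adipocytes treated with siNS, as the title of the series concerns browning of white fat under loss of Senp2. Ppargc1a (chromosome 5, 51454250 to 51567726, minus strand) encodes a coactivator of mitochondrial and thermogenic genes. In aKO cultures it rose by 1.96 ± 0.28 and 2.65 ± 0.34 in eWAT and iWAT (edgeR QL adjusted p = 6.76e-06 and 2.35e-06). Pparg, the main transcription factor of adipocyte differentiation, rose by 0.60 ± 0.14 and 0.63 ± 0.16, and Cebpa, which acts with it, by 0.65 ± 0.17 and 0.71 ± 0.19. Adipoq, which encodes adiponectin, was 1.17 ± 0.28 in eWAT and 0.91 ± 0.30 in iWAT, past the threshold in eWAT (edgeR QL adjusted p = 0.00627 and 0.0501; the iWAT value is 0.0233 without the shallow library). With a replicate block the edgeR QL adjusted p of Adipoq in iWAT was 0.0377, with the stricter filter 0.0430 and by voom 6.64e-04. Of 11 genes on chromosome 16 around and including Adipoq, whose promoter names the Cre line, 3 rose and 2 fell in eWAT and 4 rose and 2 fell in iWAT (5 and 9 adjusted over the list alone). The neighbour Eif4a2 rose (0.63 ± 0.083 and 0.66 ± 0.088). The list was fixed because a Cre transgene can carry copies of such genes, which limits what the Adipoq value means. The list was not called (median 0.067, camera adjusted p = 0.129 in eWAT; median 0.30, camera adjusted p = 0.599 in iWAT). Fgf21, a secreted metabolic hormone, fell (-1.27 ± 0.33 and -2.0 ± 0.51), although its value in iWAT had an edgeR QL adjusted p of 0.0581 without iWAT Cont siNS replicate 1 and 0.0879 without iWAT aKO siNS replicate 3. In iWAT the edgeR QL adjusted p of Pparg was 0.0727 without iWAT Cont siNS replicate 1 and 0.180 without iWAT aKO siNS replicate 3, and that of Cebpa 0.0645 without iWAT Cont siNS replicate 1 and 0.163 without iWAT aKO siNS replicate 3. In eWAT that of Cebpa was 0.0612 without eWAT Cont siNS replicate 1 and 0.0549 without eWAT aKO siNS replicate 3. With the 6 iWAT libraries alone the edgeR QL adjusted p was 0.121 for Pparg and 0.0624 for Cebpa. The brown fat gene Ucp1 had 1 count in all 24 libraries together, in iWAT aKO siCEBPb, and Cidea had 4 counts, so neither was tested. Dio2, Prdm16, Elovl3, Cox7a1 and Cox8b, other genes tied to brown fat, did not pass in eWAT (-0.21, -0.29, -0.81, 0.21 and 1.1). Prdm16 passed by voom (adjusted p = 0.0225), and Elovl3 with the 6 eWAT libraries alone (edgeR QL adjusted p = 0.0388).

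Many large changes were found in both depots. Ptn, which encodes the growth factor pleiotrophin, rose by 3.39 ± 0.55 and 2.90 ± 0.67 (in iWAT, edgeR QL adjusted p = 0.0629 without iWAT aKO siNS replicate 1), Comp, a cartilage matrix protein, by 2.75 ± 0.15 and 2.95 ± 0.18 and Clec3b, which encodes tetranectin, by 2.78 ± 0.25 and 2.75 ± 0.30 in eWAT and iWAT. Wdr72 (2.62 ± 0.23 and 2.88 ± 0.29), the granin Scg2 (2.56 ± 0.24 and 2.47 ± 0.28) and Tmem158 (2.27 ± 0.21 and 2.34 ± 0.26) also rose in both. Apod, which encodes a lipid-binding lipocalin, rose by 2.26 ± 0.13 in eWAT, as did Gsta4, a glutathione transferase (2.27 ± 0.24), and Ntrk2, a neurotrophin receptor, by 2.21 ± 0.30 in iWAT. Large falls were in Wt1, a transcription factor of mesothelium and of visceral fat precursors (-3.23 ± 0.14 and -3.29 ± 0.18), and Star, which carries cholesterol into mitochondria for steroid synthesis (-2.76 ± 0.13 and -2.68 ± 0.16). Gabra3 (-2.45 ± 0.18 and -2.48 ± 0.21) and Gria4 (-2.40 ± 0.20 and -2.50 ± 0.24), subunits of neurotransmitter receptors, fell in both depots, as did Ccbe1 (-2.43 ± 0.14 and -2.47 ± 0.16) and Adcyap1r1 (-2.37 ± 0.15 and -2.53 ± 0.18). Des, the muscle filament desmin, fell (-2.05 ± 0.15 and -2.46 ± 0.19). For each gene named for the size of its change, the 3 aKO and the 3 Cont libraries did not overlap.

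Genes of fat cell function were higher as groups in eWAT. In cholesterol synthesis 20 of 24 genes rose in eWAT and 15 in iWAT, or 21 and 18 adjusted over the list alone, among them Mvk (0.60 ± 0.074 and 0.54 ± 0.085) and Tm7sf2 (0.82 ± 0.10 and 0.99 ± 0.12). The list was called in eWAT (median 0.39, camera adjusted p = 4.17e-12, adjusted p = 0.0394 with an estimated correlation) and in iWAT (median 0.35, camera adjusted p = 5.07e-06, adjusted p = 0.193 with an estimated correlation). Adipocyte differentiation genes had 13 rises and 1 fall among 36 in eWAT and 7 rises in iWAT, or 17 and 14 changes adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, rose by 1.33 ± 0.24 in eWAT, and Mgll, a monoglyceride lipase, by 0.59 ± 0.11. Camera on differentiation genes gave adjusted p = 2.93e-06, 0.367 with an estimated correlation in eWAT and adjusted p = 0.0186, 0.791 with an estimated correlation in iWAT. In iWAT the call was lost without single libraries (camera adjusted p = 0.194 without iWAT Cont siNS replicate 1, 0.0917 without iWAT aKO siNS replicate 1 and 0.408 without iWAT aKO siNS replicate 3). Markers of several other cell types fell beside them. Brown and beige fat genes were called in eWAT (7 rose, 3 fell of 31, 12 adjusted over the list alone; median 0.21, camera adjusted p = 0.0383, adjusted p = 0.357 with an estimated correlation), where Tbx1, a beige precursor marker, rose by 3.20 ± 0.38 and Fabp3 by 1.0 ± 0.21. That call was lost when libraries were left out (camera adjusted p = 0.0560 without eWAT Cont siNS replicate 1, 0.0584 without eWAT Cont siNS replicate 2 and 0.0705 without eWAT aKO siNS replicate 2). In iWAT this list was not called (5 rose, 2 fell, 13 adjusted over the list alone; median 0.25, camera adjusted p = 0.125).

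Mitochondrial energy genes rose in part in eWAT. Nuclear genes of the respiratory chain had 18 rises among 76 (29 adjusted over the list alone), fatty acid oxidation 9 rises and 1 fall among 27 (14 adjusted over the list alone), and the citric acid cycle 6 among 20 (6 adjusted over the list alone). Camera called the 3 lists upward (adjusted p = 7.69e-05, 0.586 with an estimated correlation for respiration; adjusted p = 4.77e-05, 0.367 with an estimated correlation for oxidation; adjusted p = 9.69e-04, 0.367 with an estimated correlation for the cycle), with Etfb, an electron carrier of fatty acid oxidation, at 0.81 ± 0.16. In iWAT 0 of the 76 respiratory genes passed the edgeR QL test and 0 adjusted over the list alone, yet camera called the list downward although its median was 0.044 and its mean 0.053 (adjusted p = 0.00159, 0.798 with an estimated correlation). Without iWAT aKO siNS replicate 2 that call turned upward (list oxphos_nuclear, iWAT aKO vs Cont, siNS, adjusted p = 1.05e-04). Ribosomal protein genes, 0 of 76 changed adjusted over the list alone, were called downward in iWAT (median -0.29, camera adjusted p = 2.22e-08, adjusted p = 0.599 with an estimated correlation), but not without that library (camera adjusted p = 0.0883). In that library they held 0.883% of counts against 2.48% to 3.41% in the others.

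Cell cycle and glycolysis genes fell in both depots. Of 36 cell cycle genes 32 fell in eWAT and 30 in iWAT, or 33 and 33 adjusted over the list alone, with Mki67, a marker of dividing cells, at -0.74 ± 0.078 and -0.80 ± 0.085. The calls were median -0.53, camera adjusted p = 3.48e-21, adjusted p = 0.0394 with an estimated correlation in eWAT and median -0.55, camera adjusted p = 1.60e-15, adjusted p = 0.123 with an estimated correlation in iWAT. Among 21 glycolysis genes 14 fell in eWAT and 17 in iWAT (17 and 19 adjusted over the list alone), with the lactate transporter Slc16a3 at -1.28 ± 0.073 and -1.38 ± 0.08 and the glucose transporter Slc2a1 at -0.73 ± 0.066 and -0.81 ± 0.072. Camera gave adjusted p = 6.34e-12, 0.00858 with an estimated correlation in eWAT, and adjusted p = 2.32e-08, 0.0445 with an estimated correlation in iWAT. Targets of ATF4, the transcription factor of the amino acid stress response, had 13 falls among 28 in each depot and 1 rise in eWAT (14 and 13 changed adjusted over the list alone), including Cth (-0.96 ± 0.13 and -0.78 ± 0.16). Camera on ATF4 targets gave adjusted p = 5.87e-04, 0.0259 with an estimated correlation in eWAT and adjusted p = 0.00495, 0.0781 with an estimated correlation in iWAT, and 0.0526 without iWAT aKO siNS replicate 1. With the 6 iWAT libraries alone the edgeR QL adjusted p of Cth was 0.0687.

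Markers of the visceral depot and of other cell types were lower in aKO libraries. Of 9 visceral depot genes 5 fell in each depot (5 and 5 adjusted over the list alone), among them the transcription factors Tcf21 (-2.55 ± 0.25 and -2.72 ± 0.32) and Hoxa5 (-1.09 ± 0.14 and -1.09 ± 0.18) and thrombomodulin, Thbd (-1.70 ± 0.11 and -1.77 ± 0.14). Camera gave adjusted p = 1.36e-05, 0.0199 with an estimated correlation in eWAT, and adjusted p = 4.96e-04, 0.0781 with an estimated correlation in iWAT. Subcutaneous depot genes had 5 rises and 2 falls among 11 in eWAT and 5 and 1 in iWAT (8 in each changed adjusted over the list alone), with Irx3 at 0.76 ± 0.13 and 0.97 ± 0.15. Camera called them upward, with adjusted p = 0.0145, 0.147 with an estimated correlation in eWAT (0.0584 without eWAT Cont siNS replicate 2) and adjusted p = 0.0214, 0.193 with an estimated correlation in iWAT (0.0839 without iWAT aKO siNS replicate 1 and 0.0846 without iWAT aKO siNS replicate 3). Leukocyte markers had 12 falls among 25 in each depot and 1 rise in eWAT (14 and 15 changed adjusted over the list alone), with the macrophage receptors Cd163 (-1.50 ± 0.18 and -1.26 ± 0.22) and Fcgr1 (-1.50 ± 0.23 and -1.74 ± 0.27). Camera on leukocyte markers gave adjusted p = 2.40e-04, 0.367 with an estimated correlation in eWAT and adjusted p = 8.07e-05, 0.476 with an estimated correlation in iWAT. Endothelial markers (6 and 5 of 12 fell, 8 and 9 changed adjusted over the list alone) included Cdh5 at -1.71 ± 0.23 and -1.40 ± 0.29, while Tek rose (0.86 ± 0.12 and 1.24 ± 0.14). Camera on endothelial markers gave adjusted p = 0.0140, 0.0814 with an estimated correlation in eWAT and adjusted p = 0.0232, 0.160 with an estimated correlation in iWAT, and 0.0796 without iWAT Cont siNS replicate 2, 0.105 without iWAT aKO siNS replicate 1 and 0.143 without iWAT aKO siNS replicate 3. Smooth muscle and pericyte markers fell in 3 and 5 of 14 cases and rose in 1 (4 and 7 adjusted over the list alone). Camera on smooth muscle markers gave adjusted p = 0.00210, 0.0754 with an estimated correlation in eWAT and adjusted p = 0.0186, 0.193 with an estimated correlation in iWAT, and 0.122 without iWAT aKO siNS replicate 3. Mesothelial markers were called in iWAT, where 4 of 9 fell, including the keratins Krt19 (-1.13 ± 0.18) and Krt7 (-1.68 ± 0.37), 1 rose and 5 changed adjusted over the list alone (median -0.96, camera adjusted p = 0.0186, adjusted p = 0.215 with an estimated correlation). Left-out libraries gave a camera adjusted p of 0.0839 without iWAT aKO siNS replicate 1 and 0.0705 without iWAT aKO siNS replicate 3. In eWAT mesothelial markers were not called (3 fell, 1 rose, 4 adjusted over the list alone; median -0.89, camera adjusted p = 0.0507).

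Over all 14785 tested genes, 3013 changed in eWAT (1405 rose, 1608 fell) and 2243 in iWAT (1082 rose, 1161 fell). Without the shallow library the counts were 3857 (1901 and 1956) and 2752 (1341 and 1411). The 3 aKO and 3 Cont libraries did not overlap in 39.3% of genes in eWAT and 25.8% in iWAT, where chance gives 10%. Across the genes changed in eWAT, fold changes in the 2 depots had r = 0.936 and rho = 0.947 across genes, which are not independent replicates, and 97.9% had the same sign. Over all tested genes r was 0.755. Both depots had 836 genes higher, where independent lists would share 103, and 957 lower, where they would share 126. The lists are not independent, as same-numbered eWAT and iWAT libraries shared deviations from group means (mean r = 0.332, 11 pairs). These gave an estimated 0.00269 of the covariance of 0.0648 between depot log2 fold changes (8270 genes, without the shallow library). Sharing by whole groups was not counted. Without iWAT aKO siNS replicate 3 the iWAT count was 1436, and with the iWAT Cont and aKO siNS libraries alone it was 718.

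**Figure D3:**
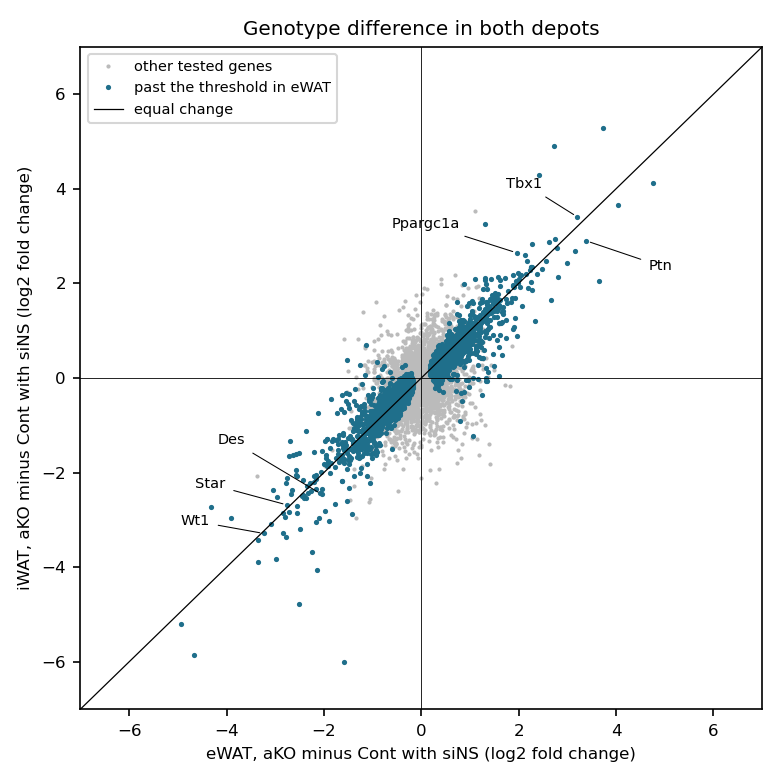
Log2 fold change of aKO minus Cont with siNS for each tested gene, eWAT on the horizontal and iWAT on the vertical axis, with genes past the threshold in eWAT in blue, others in grey, and a line of equal change. Across the 3013 blue genes r was 0.936, with Ptn at 3.39 and Wt1 at -3.23 in eWAT.

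The second question concerned knockdown of Cebpb, an early transcription factor of adipocyte differentiation, in Cont cultures. Cebpb fell in eWAT and iWAT (-1.73 ± 0.16 and -1.79 ± 0.17; edgeR QL adjusted p = 4.25e-08 and 6.96e-08). Cebpa fell (-0.79 ± 0.18 and -0.92 ± 0.19), as did Elovl3, a fatty acid elongase (-1.57 ± 0.40 and -1.68 ± 0.42). Fgf21 rose (1.89 ± 0.22 and 1.91 ± 0.26), with Ebf2, a transcription factor of brown precursors (0.70 ± 0.10 and 0.63 ± 0.11), and Hoxc10 (0.55 ± 0.095 and 0.55 ± 0.097). Ppargc1a did not pass (-0.06 ± 0.36 and 0.26 ± 0.44; edgeR QL adjusted p = 0.933 and 0.769).

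Large falls were found in both depots. F13a1, the A chain of coagulation factor XIII, fell (-6.40 ± 0.19 and -6.46 ± 0.21), with Serpina3m (-6.08 ± 0.44 and -5.84 ± 0.49), Lyz1 (-4.30 ± 0.30 and -4.19 ± 0.33), Lcn2, which encodes lipocalin 2 (-4.11 ± 0.36 and -4.51 ± 0.40), and Ccl6, a chemokine (-3.87 ± 0.17 and -4.19 ± 0.18). Lyz1 and Serpina3m have close paralogs, and reads without a unique alignment stood in a counter line apart from the genes (2.77% to 4.38% of reads in 23 libraries). Of 25 leukocyte markers 23 fell in eWAT and 22 in iWAT (23 and 24 adjusted over the list alone), with Cd163 at -5.13 ± 0.29 and -4.97 ± 0.32 and the integrin Itgam at -3.31 ± 0.21 and -2.94 ± 0.22. The calls were median -1.72, camera adjusted p = 1.59e-18, adjusted p = 0.0684 with an estimated correlation in eWAT and median -1.89, camera adjusted p = 1.60e-18, adjusted p = 0.0685 with an estimated correlation in iWAT. Inflammatory genes had 18 falls and 6 rises among 32 in eWAT and 18 and 5 in iWAT (25 and 24 adjusted over the list alone). Camera on inflammatory genes gave adjusted p = 1.48e-04, 0.147 with an estimated correlation in eWAT and adjusted p = 3.94e-04, 0.162 with an estimated correlation in iWAT. The cytokine Lif was among those that rose (1.04 ± 0.097 and 0.99 ± 0.11). Large rises included Ptn (3.86 ± 0.52 and 3.52 ± 0.58), Col8a2, a short-chain collagen (3.38 ± 0.13 and 3.42 ± 0.15), C1qtnf3 (2.49 ± 0.11 and 2.55 ± 0.11) and Tnmd, which encodes tenomodulin (2.28 ± 0.21 and 2.41 ± 0.24).

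Interferon response genes, ATF4 targets and smooth muscle genes rose in both depots. Among 35 interferon response genes 26 rose in eWAT and 27 in iWAT (27 and 27 adjusted over the list alone), such as Ifit3 (1.87 ± 0.18 and 1.87 ± 0.19), and its near-identical neighbour Ifit3b (1.68 ± 0.17 and 1.55 ± 0.18). Camera on interferon genes gave adjusted p = 4.58e-14, 0.127 with an estimated correlation in eWAT and adjusted p = 1.71e-14, 0.130 with an estimated correlation in iWAT. ATF4 targets had 24 and 22 rises and 1 and 2 falls among 28 (25 and 24 changed adjusted over the list alone), including Chac1, a glutathione-degrading enzyme (1.63 ± 0.11 and 1.35 ± 0.12), and the amino acid transporter Slc7a5 (1.45 ± 0.098 and 1.39 ± 0.1). Camera on ATF4 targets gave adjusted p = 3.68e-16, 1.39e-05 with an estimated correlation in eWAT and adjusted p = 2.26e-14, 3.27e-05 with an estimated correlation in iWAT. Of 14 smooth muscle and pericyte markers 10 rose and 1 fell in each depot (12 changed adjusted over the list alone), with smooth muscle myosin Myh11 at 1.91 ± 0.14 and 1.95 ± 0.14. Camera on smooth muscle markers gave adjusted p = 2.26e-08, 0.00186 with an estimated correlation in eWAT and adjusted p = 1.04e-07, 0.00301 with an estimated correlation in iWAT. Hox genes rose in 14 and 7 of 30 cases (16 and 7 adjusted over the list alone), with Hoxc8 at 0.65 ± 0.081 and 0.68 ± 0.083. Camera on Hox genes gave adjusted p = 6.30e-05, 0.00186 with an estimated correlation in eWAT and adjusted p = 4.37e-04, 0.00486 with an estimated correlation in iWAT. Subcutaneous depot genes had 7 and 8 rises among 11 (9 changed adjusted over the list alone in each; camera adjusted p = 5.55e-04, 0.0466 with an estimated correlation; in iWAT adjusted p = 4.37e-04, 0.0401 with an estimated correlation), with Irx3 at 0.93 ± 0.12 and 0.96 ± 0.14, while Sfrp2, a secreted Wnt regulator, fell (-1.20 ± 0.15 and -1.17 ± 0.15).

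Genes of lipid storage, glycolysis and cell division fell beside the leukocyte markers. Lipogenesis genes had 15 and 17 falls among 24 (19 and 18 adjusted over the list alone), with Dgat2, which makes triglycerides, at -1.93 ± 0.25 and -2.02 ± 0.26. Camera on lipogenesis genes gave adjusted p = 3.65e-07, 0.186 with an estimated correlation in eWAT and adjusted p = 1.04e-07, 0.162 with an estimated correlation in iWAT. Adipocyte differentiation genes fell in 12 and 14 of 36 cases and rose in 3 and 2 (16 and 18 adjusted over the list alone), with the adipokine gene Retn at -2.03 ± 0.34 and -2.08 ± 0.36. Camera on differentiation genes gave adjusted p = 0.00121, 0.576 with an estimated correlation in eWAT and adjusted p = 4.37e-04, 0.521 with an estimated correlation in iWAT. Genes of cAMP-driven lipolysis fell in 9 and 7 of 18 cases (12 and 9 adjusted over the list alone), led by the adenosine receptor Adora1 (-3.29 ± 0.45 and -2.91 ± 0.45). Camera on lipolysis genes gave adjusted p = 4.95e-04, 0.186 with an estimated correlation in eWAT and adjusted p = 0.00464, 0.304 with an estimated correlation in iWAT. Among 21 identifiers of the glycolysis list 17 fell in each depot (17 adjusted over the list alone). Camera on glycolysis genes gave adjusted p = 2.08e-12, 0.00192 with an estimated correlation in eWAT and adjusted p = 6.47e-14, 0.00204 with an estimated correlation in iWAT. Cell cycle genes fell in 31 and 32 of 36 cases (31 and 35 adjusted over the list alone; camera adjusted p = 4.34e-13, 0.125 with an estimated correlation; in iWAT adjusted p = 1.85e-12, 0.130 with an estimated correlation), with Top2a at -0.69 ± 0.076 and -0.59 ± 0.077. Over all tested genes 3958 changed in eWAT (1750 rose, 2208 fell) and 3597 in iWAT (1522 rose, 2075 fell), or 4753 and 4360 without the shallow library. Groups did not overlap in 45.9% and 42.8% of genes, where chance gives 10%.

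The same knockdown in aKO adipocytes was the third comparison. Cebpb fell in eWAT and iWAT (-2.47 ± 0.17 and -2.69 ± 0.19; edgeR QL adjusted p = 3.22e-10 and 6.88e-10). Cebpa (-1.62 ± 0.18 and -1.74 ± 0.20), Pparg (-0.69 ± 0.14 and -0.61 ± 0.16) and Fabp4, the fatty acid-binding protein of adipocytes (-1.20 ± 0.27 and -1.0 ± 0.28), fell in both depots. In iWAT the falls of Pparg and Fabp4 had an edgeR QL adjusted p of 0.126 without iWAT aKO siNS replicate 3 and 0.0617 without iWAT aKO siNS replicate 3 respectively, and that of Fabp4 was 0.0561 with the 6 libraries alone. Ppargc1a fell (-1.80 ± 0.27 and -1.83 ± 0.28), as did Elovl3 (-2.41 ± 0.59 and -2.81 ± 0.52). Fgf21 rose (2.66 ± 0.28 and 3.26 ± 0.41), with Ebf2 (0.71 ± 0.10 and 0.66 ± 0.11). The largest rises included Gjb2, which encodes connexin 26 (5.04 ± 0.55 and 4.0 ± 0.57), Ptgs2, which makes prostaglandins (2.89 ± 0.33 and 2.67 ± 0.37), Nrg1, a growth factor (2.88 ± 0.11 and 3.04 ± 0.14), and Ankrd1 (2.63 ± 0.23 and 2.90 ± 0.28). Among the largest falls were Lcn2 (-5.72 ± 0.58 and -5.05 ± 0.60), Traf1 (-5.23 ± 0.41 and -4.53 ± 0.42) and Ccl6 (-5.18 ± 0.25 and -4.81 ± 0.27).

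Adipocyte gene groups fell in aKO cells with the knockdown. Of 36 adipocyte differentiation genes 25 fell in eWAT and 23 in iWAT and 2 rose in each (29 and 28 adjusted over the list alone), with Slc2a4 at -2.39 ± 0.28 in eWAT and lipoprotein lipase, Lpl, at -2.07 ± 0.25 in iWAT. Camera on differentiation genes gave adjusted p = 3.59e-09, 0.257 with an estimated correlation in eWAT and adjusted p = 5.88e-06, 0.499 with an estimated correlation in iWAT. Lipogenesis genes fell in 18 and 19 of 24 cases (19 in each adjusted over the list alone), with Dgat2 at -2.72 ± 0.25 and -2.78 ± 0.27. Camera on lipogenesis genes gave adjusted p = 1.17e-08, 0.161 with an estimated correlation in eWAT and adjusted p = 5.28e-07, 0.276 with an estimated correlation in iWAT. Lipolysis genes fell in 14 and 12 of 18 cases (14 and 13 adjusted over the list alone). Camera on lipolysis genes gave adjusted p = 8.22e-06, 0.116 with an estimated correlation in eWAT and adjusted p = 1.63e-04, 0.224 with an estimated correlation in iWAT. In eWAT 12 of 27 fatty acid oxidation genes fell (12 adjusted over the list alone; camera adjusted p = 0.00181, 0.531 with an estimated correlation), including Acsl1, which activates fatty acids (-1.75 ± 0.28), and 10 of 20 citric acid cycle genes (10 adjusted over the list alone; camera adjusted p = 0.00737, 0.531 with an estimated correlation). Leukocyte markers fell beside them in 24 and 22 of 25 cases (24 in each adjusted over the list alone), with Itgam at -5.07 ± 0.34 and -4.53 ± 0.34. Camera on leukocyte markers gave adjusted p = 3.25e-20, 0.0595 with an estimated correlation in eWAT and adjusted p = 2.23e-14, 0.149 with an estimated correlation in iWAT.

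Stress, contractile and interferon genes rose in aKO cells too. ATF4 targets had 22 and 20 rises and 1 fall in each depot among 28 (24 and 23 changed adjusted over the list alone), with Cth at 2.13 ± 0.12 and 2.05 ± 0.14 and Chac1 at 2.09 ± 0.11 and 1.92 ± 0.13. Camera on ATF4 targets gave adjusted p = 3.07e-12, 8.48e-05 with an estimated correlation in eWAT and adjusted p = 1.91e-09, 4.64e-04 with an estimated correlation in iWAT. Smooth muscle markers rose in 10 of 14 cases in each depot (10 and 11 changed adjusted over the list alone), with Myh11 at 2.69 ± 0.15 and 2.52 ± 0.17. Camera on smooth muscle markers gave adjusted p = 1.20e-09, 0.00115 with an estimated correlation in eWAT and adjusted p = 5.28e-07, 0.00668 with an estimated correlation in iWAT. Interferon response genes rose in 27 and 26 of 35 cases (28 and 27 adjusted over the list alone). Camera on interferon genes gave adjusted p = 1.54e-11, 0.161 with an estimated correlation in eWAT and adjusted p = 1.44e-09, 0.276 with an estimated correlation in iWAT. SUMO pathway genes were called upward in eWAT, where 10 of 26 rose and 1 fell (11 adjusted over the list alone; median 0.13, camera adjusted p = 0.00434, adjusted p = 0.0256 with an estimated correlation). The SUMO protease Senp5 rose (0.80 ± 0.088), as did the SUMO-binding protein Daxx (0.58 ± 0.069).

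Knockdown changed 5274 genes in eWAT aKO (2457 rose, 2817 fell) and 4624 in iWAT aKO (2013 rose, 2611 fell), or 6099 and 5199 without the shallow library. Groups did not overlap in 46.3% and 35.1% of genes, against 10% by chance. Across genes changed in Cont, the knockdown effects in Cont and aKO, which share no library, had r = 0.888 (rho = 0.881) in eWAT and r = 0.893 (rho = 0.896) in iWAT, and 90.9% and 92.3% had the same sign. Over all tested genes r was 0.791 and 0.774. In iWAT aKO camera called respiratory chain and ribosomal protein genes upward, with 4 falls, 1 change adjusted over the list alone, a median of -0.11 and a mean of -0.11 for the first (camera adjusted p = 0.00966, 0.878 with an estimated correlation), and 0 changes adjusted over the list alone and a median of 0.081 for the second (camera adjusted p = 6.82e-04, 0.859 with an estimated correlation). Without iWAT aKO siNS replicate 2 both calls turned downward (list oxphos_nuclear, iWAT siCEBPb vs siNS, aKO, adjusted p = 5.08e-04; list ribosomal_protein, iWAT siCEBPb vs siNS, aKO, adjusted p = 9.28e-04). The iWAT count was 2231 with the 6 libraries of the comparison alone.

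The fourth comparison was between aKO and Cont adipocytes when both received siCEBPb. Cebpb itself was lower in aKO (-0.88 ± 0.17 and -0.97 ± 0.19 in eWAT and iWAT; edgeR QL adjusted p = 0.00134 and 0.00155). Wt1 (-3.42 ± 0.15 and -3.18 ± 0.15), Gdpd2 (-3.35 ± 0.22 and -3.50 ± 0.26) and complement C7 (-2.77 ± 0.25 and -3.24 ± 0.28) had large falls. Comp (1.87 ± 0.17 and 1.98 ± 0.20) and Wdr72 (1.78 ± 0.21 and 1.93 ± 0.22) rose. Prl2c2 (1.58 ± 0.25 and 1.68 ± 0.26) and Prl2c3 (1.90 ± 0.40 and 1.86 ± 0.40), members of the prolactin family, rose too, but they are near-identical copies whose reads cannot be told apart with certainty. Ppargc1a did not pass here (0.22 ± 0.35 and 0.56 ± 0.37; edgeR QL adjusted p = 0.816 and 0.474). Pparg was 0.19 ± 0.15 and 0.081 ± 0.15, not past the threshold, and Hoxc10 rose in eWAT (0.41 ± 0.09) and was 0.22 ± 0.09 in iWAT (edgeR QL adjusted p = 0.147, 0.0243 with the 6 libraries alone, voom adjusted p = 0.0498).

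Visceral, mesothelial, endothelial and leukocyte markers were lower in aKO. Visceral and mesothelial lists share Wt1 and other genes and are not independent. Of 9 visceral depot genes 8 fell in eWAT and 6 in iWAT (8 and 9 adjusted over the list alone), with Tcf21 at -4.24 ± 0.29 and -2.62 ± 0.27. Camera on visceral genes gave adjusted p = 6.04e-14, 2.37e-04 with an estimated correlation in eWAT and adjusted p = 6.02e-13, 3.71e-04 with an estimated correlation in iWAT. Mesothelial markers fell in 7 and 5 of 9 cases (7 in each adjusted over the list alone). Camera on mesothelial markers gave adjusted p = 4.22e-08, 0.00636 with an estimated correlation in eWAT and adjusted p = 6.36e-08, 0.00518 with an estimated correlation in iWAT. Leukocyte markers fell in 20 of 25 cases in each depot (23 and 21 adjusted over the list alone), with the complement gene C1qb at -2.12 ± 0.25 and -2.25 ± 0.27. Camera on leukocyte markers gave adjusted p = 6.04e-22, 0.0347 with an estimated correlation in eWAT and adjusted p = 1.92e-23, 0.0279 with an estimated correlation in iWAT. Endothelial markers fell in 5 and 8 of 12 cases (6 and 9 adjusted over the list alone), with Pecam1 at -1.56 ± 0.25 and -1.87 ± 0.25. Camera on endothelial markers gave adjusted p = 6.19e-05, 0.00636 with an estimated correlation in eWAT and adjusted p = 3.29e-07, 0.00114 with an estimated correlation in iWAT. In eWAT 7 of 20 fibroblast and progenitor markers fell and 1 rose (10 adjusted over the list alone; median -0.17, camera adjusted p = 0.0259, adjusted p = 0.335 with an estimated correlation; 0.05004 without eWAT aKO siCEBPb replicate 1), with Dpp4, a marker of early progenitors, at -2.77 ± 0.35.

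Beside these markers, cholesterol synthesis genes rose and glycolysis genes fell. Cholesterol synthesis had 14 and 13 rises among 24 genes (18 in each adjusted over the list alone), with Mvk at 0.47 ± 0.072 and 0.40 ± 0.074 and Lss at 0.49 ± 0.087 and 0.44 ± 0.089. Camera on cholesterol genes gave adjusted p = 8.03e-13, 0.0282 with an estimated correlation in eWAT and adjusted p = 7.81e-13, 0.0279 with an estimated correlation in iWAT. Glycolysis genes fell in 9 and 7 of 21 cases (12 and 7 adjusted over the list alone), with Slc16a3 at -1.18 ± 0.075 and -1.12 ± 0.076. Camera on glycolysis genes gave adjusted p = 3.88e-07, 0.0193 with an estimated correlation in eWAT and adjusted p = 2.59e-07, 0.0201 with an estimated correlation in iWAT. Immediate early genes rose in 4 of 22 cases in each depot (6 and 4 adjusted over the list alone), with Egr1 at 0.31 ± 0.069 in eWAT. Camera on early genes gave adjusted p = 0.00185, 0.0193 with an estimated correlation in eWAT and adjusted p = 0.00239, 0.0201 with an estimated correlation in iWAT. Adipocyte differentiation genes were not called here (2 and 2 of 36 rose, 1 fell in each, 3 and 4 changed adjusted over the list alone; camera adjusted p = 0.380 and 0.435).

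With siCEBPb, 1592 genes changed between genotypes in eWAT (576 rose, 1016 fell) and 1483 in iWAT (521 rose, 962 fell), or 2161 and 1972 without the shallow library. Groups did not overlap in 28.9% and 31.6% of genes, against 10% by chance. Across genes changed with siNS, the genotype differences with siNS and with siCEBPb had r = 0.651 (rho = 0.615) in eWAT and r = 0.685 (rho = 0.664) in iWAT, and 74.3% and 78.0% had the same sign. Over all tested genes r was 0.479 and 0.475. In the 4 genotype comparisons 177 genes were higher and 344 lower in all. Without iWAT aKO siCEBPb replicate 1 the iWAT count was 942, and voom called 2568.

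The fifth question was whether the knockdown acted differently in aKO and Cont cells, tested as the genotype by siRNA interaction, in which a positive value means a more positive knockdown effect in aKO. Ppargc1a had negative interactions of -1.74 ± 0.46 and -2.08 ± 0.53 in eWAT and iWAT (edgeR QL adjusted p = 0.0227 and 0.0244). These calls were lost in several fits in which the values stayed negative. In eWAT the edgeR QL adjusted p was 0.0563 without eWAT Cont siNS replicate 2, 0.106 without eWAT Cont siCEBPb replicate 1, 0.0649 without eWAT Cont siCEBPb replicate 3, 0.0556 without eWAT aKO siNS replicate 3 and 0.0839 without eWAT aKO siCEBPb replicate 1. With the replicate block within depot and genotype it was 0.0561 in eWAT, at a log2 value of -1.73. In iWAT it was 0.0703 without iWAT Cont siNS replicate 1, 0.0678 without iWAT Cont siNS replicate 3, 0.0798 without iWAT Cont siCEBPb replicate 2, 0.0712 without iWAT Cont siCEBPb replicate 3, 0.0523 without iWAT aKO siNS replicate 1, 0.0633 without iWAT aKO siNS replicate 3 and 0.0664 without iWAT aKO siCEBPb replicate 1. With the groups of the comparison alone it was 0.0645 in iWAT, and the DESeq2 adjusted p was 0.0560. Clec3b (-2.90 ± 0.38 and -3.0 ± 0.46), Scg2 (-2.05 ± 0.31 and -1.98 ± 0.36), Egfl6 (-2.65 ± 0.27 and -2.43 ± 0.31), the neurotrophic factor Ndnf (-2.40 ± 0.17 and -2.68 ± 0.18) and Cyp2e1, a cytochrome P450 of adipocytes and liver (-3.45 ± 0.63 and -3.80 ± 0.68), were also negative. Ptgs2 (3.04 ± 0.44 and 2.43 ± 0.49), Ankrd1 (2.13 ± 0.31 and 2.27 ± 0.37) and the semaphorin Sema7a (2.05 ± 0.18 and 1.91 ± 0.20) were positive. In eWAT the growth factors Ereg (2.33 ± 0.42) and Inhba (1.66 ± 0.17) were positive. For Cebpb the interaction was -0.74 ± 0.22 and -0.90 ± 0.25 (edgeR QL adjusted p = 0.0563 and 0.0522) and for Cebpa -0.82 ± 0.25 and -0.82 ± 0.27 (edgeR QL adjusted p = 0.0589 and 0.106). These values passed the threshold in several other fits. With the replicate block within depot and genotype the edgeR QL adjusted p of Cebpb was 0.0440 in eWAT and 0.0362 in iWAT. With the stricter filter it was 0.0461 and 0.0447. The voom adjusted p of Cebpb was 0.00140 and 0.00728, and the DESeq2 adjusted p 0.0467 and 0.0197. Left-out libraries gave Cebpb an edgeR QL adjusted p of 0.0350 without eWAT Cont siCEBPb replicate 2, 0.0241 without eWAT aKO siCEBPb replicate 2, 0.0332 without iWAT Cont siNS replicate 1 and 0.0148 without iWAT aKO siCEBPb replicate 3. For Cebpa in eWAT the edgeR QL adjusted p was 0.0489 with a replicate block and 0.0454 with the stricter filter. It was 0.0441 without eWAT Cont siCEBPb replicate 2 and 0.0132 without eWAT aKO siCEBPb replicate 2. The DESeq2 adjusted p of Cebpa in eWAT was 0.0336. By voom Cebpa had an adjusted p of 0.00106 in eWAT and 0.0103 in iWAT. With no filter the edgeR QL adjusted p of both genes, and of Adipoq (iWAT, siNS), was at most 2.45e-06. Log2 values hardly moved, so it adds no support. Senp2 was 0.29 ± 0.10 in eWAT (edgeR QL adjusted p = 0.0855, 0.0484 without the shallow library, 0.0274 without eWAT aKO siNS replicate 1). Its voom adjusted p was 0.0108.

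Gene groups followed in eWAT. Immediate early genes had 7 positive interactions among 22 (8 adjusted over the list alone; median 0.30, camera adjusted p = 1.59e-05, adjusted p = 0.00617 with an estimated correlation), with Egr1 at 0.58 ± 0.099. Smooth muscle markers had 5 among 14 (8 adjusted over the list alone; median 0.53, camera adjusted p = 3.41e-05, adjusted p = 0.0292 with an estimated correlation), with Actg2 at 1.22 ± 0.29, and SUMO pathway genes 2 among 26 (5 adjusted over the list alone; median 0.072, camera adjusted p = 0.00615, adjusted p = 0.0344 with an estimated correlation), with Senp5 at 0.57 ± 0.12. Cell cycle genes had 11 positive interactions among 36 (15 adjusted over the list alone; median 0.31, camera adjusted p = 8.31e-11, adjusted p = 0.222 with an estimated correlation). Adipocyte differentiation genes had 3 negative interactions among 36 (5 adjusted over the list alone; median -0.60, camera adjusted p = 3.01e-07, adjusted p = 0.393 with an estimated correlation), with Klf15 at -1.0 ± 0.23, and leukocyte markers 4 among 25 beside them (16 adjusted over the list alone; median -1.02, camera adjusted p = 3.01e-07, adjusted p = 0.333 with an estimated correlation). In iWAT smooth muscle markers (4 of 14 positive, 9 adjusted over the list alone; median 0.66, camera adjusted p = 9.04e-04, adjusted p = 0.183 with an estimated correlation) and immediate early genes (5 of 22, 6 adjusted over the list alone; median 0.23, camera adjusted p = 0.0191, adjusted p = 0.200 with an estimated correlation; 0.147 without iWAT aKO siNS replicate 1 and 0.0929 without iWAT aKO siNS replicate 3) were called upward. Respiratory chain genes were called upward there with a median of -0.048 and a mean of -0.048 (camera adjusted p = 4.47e-04, 0.789 with an estimated correlation; 0 of 76 changed adjusted over the list alone). Without iWAT aKO siNS replicate 2 this call turned downward (list oxphos_nuclear, iWAT genotype by siRNA interaction, adjusted p = 0.00295).

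In eWAT 938 genes passed the interaction test (445 positive, 493 negative), or 1677 without iWAT aKO siNS replicate 2. In iWAT 519 passed (195 positive, 324 negative), or 939 without that library. The eWAT count fell to 434 without aKO siCEBPb replicate 1, to 543 and 558 without Cont siCEBPb replicates 1 and 3, and to 571 without aKO siNS replicate 3. The iWAT count fell to 291 without aKO siCEBPb replicate 1, to 304 and 344 without aKO siNS replicates 3 and 1, and to 320 and 332 without replicate 1 of Cont siCEBPb and of Cont siNS. With the replicate number as a block within depot and genotype the counts were 518 and 309.

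The last comparisons were of depots. In Cont siNS, genes higher in iWAT than eWAT included Rpl38-ps2 (1.58 ± 0.26), the noncoding RNA Bc1 (1.40 ± 0.23) and the mitochondrial gene mt-Atp6 (1.26 ± 0.26). Genes lower in iWAT included the immediate early gene Ier3 (-0.89 ± 0.16) and the splicing factor Hnrnpl (-0.79 ± 0.14). For mt-Atp6 the edgeR QL adjusted p was 0.0741 without eWAT Cont siNS replicate 2, 0.0704 without eWAT Cont siNS replicate 3, 0.114 without iWAT Cont siNS replicate 2 and 0.0965 without iWAT Cont siNS replicate 3, for Ier3 0.0524 without eWAT Cont siNS replicate 3 and 0.0639 without iWAT Cont siNS replicate 3, and for Hnrnpl 0.0537 without iWAT Cont siNS replicate 3. Processed pseudogenes such as Rpl38-ps2 resemble their parent genes and are uncertain, and they made up 52 of the 102 higher genes against 3.05% of all tested genes (Fisher's exact test, two-sided, p = 8.03e-52). Without iWAT aKO siNS replicate 2 they were 113 of 582 higher genes. None of the 9 visceral and 11 subcutaneous genes passed edgeR QL, and 0 and 2 did adjusted over the list alone, with Wt1 at -0.069 ± 0.11. Hoxc10, a gene of inguinal fat, was 0.29 ± 0.10 (edgeR QL adjusted p = 0.160, 0.0348 without the shallow library, voom adjusted p = 0.0426).

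Mitochondrially encoded genes were called higher in iWAT (4 of 13 rose, 7 adjusted over the list alone; median 0.76, camera adjusted p = 6.69e-10, adjusted p = 0.152 with an estimated correlation) and immediate early genes lower (1 of 22 fell, 9 adjusted over the list alone; median -0.20, camera adjusted p = 1.87e-07, adjusted p = 0.00104 with an estimated correlation). In iWAT Cont siNS replicates 2 and 3, 26.5% and 27.6% of reads were not aligned. Mitochondrial genes held 1.55% and 1.60% of gene counts. Replicate 1 had 18.7% and 1.199%, and eWAT Cont siNS had 18.7% to 21.01% and 0.960% to 1.01%. Yet Cont siCEBPb had 18.4% to 21.4% and 1.29% to 1.58% in iWAT, and 19.1% to 19.9% and 0.851% to 1.02% in eWAT. Extracellular matrix genes were called lower (1 of 42 fell, 2 adjusted over the list alone; median -0.18, camera adjusted p = 9.77e-09, adjusted p = 0.0519 with an estimated correlation). Over all tested genes 178 differed (102 higher and 76 lower in iWAT), or 1123 without iWAT aKO siNS replicate 2, 113 of them by at least a doubling. The count was 23 and 58 without iWAT Cont siNS replicates 3 and 2, and 39, 48 and 88 without eWAT Cont siNS replicates 3, 2 and 1. Groups did not overlap in 26.0% of genes, against 10% by chance. The depot by genotype interaction with siNS gave 0 genes with edgeR QL, DESeq2 and voom, and 415 of 14785 genes had an unadjusted p under 0.05 in edgeR QL. Camera called 5 lists there, 1 upward and 4 downward, with no gene past the threshold and 0 adjusted over each list alone. Those downward were respiratory chain genes (median -0.21, camera adjusted p = 3.23e-16, adjusted p = 0.871 with an estimated correlation), ribosomal protein genes (median -0.37, camera adjusted p = 3.36e-18, adjusted p = 0.871 with an estimated correlation), mitochondrially encoded genes (median -0.32, camera adjusted p = 0.0403, adjusted p = 0.871 with an estimated correlation) and fatty acid oxidation genes (median -0.027, camera adjusted p = 0.0403, adjusted p = 0.871 with an estimated correlation). Extracellular matrix genes were called upward (median 0.12, camera adjusted p = 0.00267, adjusted p = 0.871 with an estimated correlation). Left-out libraries gave a camera adjusted p of 0.0784 without eWAT Cont siNS replicate 3, 0.0544 without eWAT aKO siNS replicate 1, 0.0829 without eWAT aKO siNS replicate 2, 0.0952 without iWAT Cont siNS replicate 2, 0.179 without iWAT Cont siNS replicate 3, 0.520 without iWAT aKO siNS replicate 2 and 0.115 without iWAT aKO siNS replicate 3 for mitochondrially encoded genes. For oxidation it was 0.157 without eWAT Cont siNS replicate 1, 0.253 without eWAT aKO siNS replicate 3, 0.122 without iWAT Cont siNS replicate 2, 0.0528 without iWAT Cont siNS replicate 3, 0.108 without iWAT aKO siNS replicate 1 and 0.862 without iWAT aKO siNS replicate 2, and for the matrix 0.0606 without iWAT aKO siNS replicate 2. Ppargc1a was 0.69 ± 0.48 in the depot by genotype test (edgeR QL adjusted p = 1.00).

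**Figure D4:**
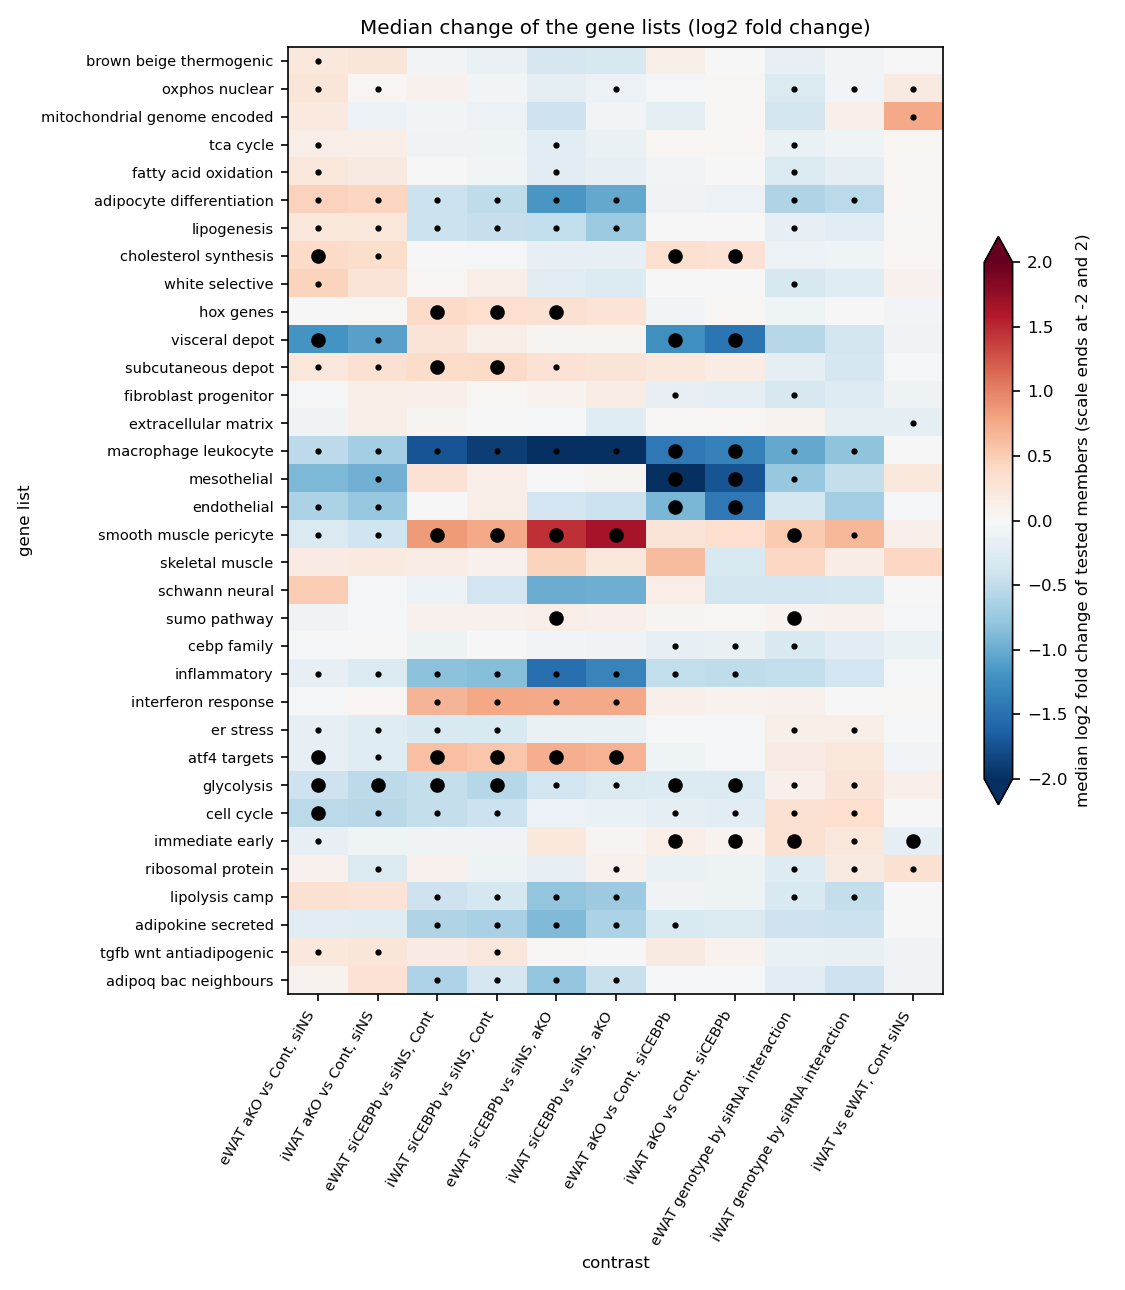
Median log2 fold change of the tested members of each gene list (vertical) in 11 contrasts (horizontal), with the colour scale ending at -2 and 2. Small dots mark camera calls and large dots calls that also hold with an estimated correlation, 40 of 157 over 12 contrasts, and leukocyte markers ranged down to -2.77 in iWAT aKO with siCEBPb.

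Of the 157 list calls made by camera over the 12 contrasts, 40 held with an estimated correlation between genes. They were cholesterol synthesis, visceral, ATF4, glycolysis and cell cycle lists in eWAT aKO with siNS and glycolysis in iWAT. With siCEBPb in Cont they were Hox, subcutaneous, smooth muscle, ATF4 and glycolysis lists in both depots. In aKO they were smooth muscle and ATF4 lists in both depots, with Hox and SUMO lists in eWAT. Between genotypes with siCEBPb they were cholesterol synthesis, visceral, mesothelial, endothelial, leukocyte, glycolysis and immediate early lists in both depots. In the eWAT interaction smooth muscle, SUMO and immediate early lists held, and in the depot comparison the immediate early list.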

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

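Tests on shared deviations and on visceral, mesothelial and leukocyte genes were chosen after those results were seen, and counts over other splits were planned.

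A difference between groups drew attention to the genotype by siRNA interactions, since the effect of siCEBPb differed between aKO and Cont in 938 genes in eWAT and 519 in iWAT (edgeR QL). With siCEBPb, Cebpb was at 50.4 CPM in eWAT Cont and 27.4 in eWAT aKO, and at 36.0 and 18.5 in iWAT. The interaction therefore cannot tell a response that differs by genotype from a deeper knockdown in aKO. In eWAT 1 of 33 splits of the libraries, the real one, gave as many genes, and the highest other split gave 888. In iWAT 2 of 33 splits gave as many, the other with 2412. The splits exchange siNS and siCEBPb libraries, and knockdown changed 3958 and 5274 genes in eWAT and 3597 and 4624 in iWAT, so these counts decide nothing about chance. The highest other splits moved libraries of 1 genotype alone, replicates 1 and 3 of aKO siNS and aKO siCEBPb in eWAT and replicates 1 and 3 of Cont siNS with 1 and 2 of Cont siCEBPb in iWAT, so they follow the siRNA structure of the samples.

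A sample far from the others was iWAT aKO siNS replicate 2, in which 93.3% of reads were not aligned, in counter lines that no comparison uses.

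Libraries of the 2 depot labels shared their deviations from group means. Pairing eWAT with iWAT libraries by replicate number gave a mean r of 0.332 over 11 pairs, as high as in 1 of 1296 pairings (exact share 7.72e-04, the smallest these pairings can give), with 0.317 the highest other, as the same cells or RNA behind both labels would give. A single library under both names is excluded, since the lowest chi-square per gene of a same-numbered pair was 4.96 against 1.68 between replicates of a group, with medians of 8.87 and 4.21, so such pairs were at the median less alike than replicates. Cells of 2 depots that shared a culture day or position cannot be told apart from the same cells, because a bound on depot genes rests on an assumed profile. Library iWAT aKO siNS replicate 2 was left out of all values pooled over groups. Over 16 expressed visceral and subcutaneous genes the pooled depot difference then lay within 0.443 (95% bound, log2, Hoxc9). The 4 that passed went the way the depot labels give, and the others did not pass. The subcutaneous genes Hoxc9 (0.342), Hoxc10 (0.207) and Shox2 (0.121) were higher in iWAT, and the visceral gene Nr2f1 (-0.131) was lower. As these differences were small, a hypothesis is that the depot labels may cover similar cells.

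Camera called visceral genes lower in aKO with either siRNA, and mesothelial genes with siCEBPb. With siNS the latter were called in iWAT alone and not without some single libraries. A whole exchange of epididymal and inguinal cells between genotype labels cannot be told from a genotype effect. The bound on subcutaneous genes rests on an assumed depot profile. Of 11 subcutaneous genes 8 lay above 0 and 2 below in aKO minus Cont (median 0.147, SE of the median 0.139, log2). A lower share of mesothelial cells in aKO cultures stays open. Of 11 markers 8 lay below 0 and 2 had intervals over 0. Igfbp6 lay above 0, with a baseline (mean log2 CPM 7.94, others down to -1.98) that would hide a small share. Loss of Senp2 in adipocytes stays open too, as pooled Senp2 counts differed by -0.0321 (SE 0.0355, log2) and include reads outside the deleted part.

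Leukocyte genes fell with siCEBPb in each depot and genotype. The falls were unequal, as 8 of 25 members lay 1 or more (log2) from the list median of -2.22 with an interval that left it out. Members ran from -5.47 for Cd163 to 0.61 for H2-Eb1, which was at a low level (mean log2 CPM -0.25). An even loss of leukocytes that alone express the markers would give equal falls, which were not seen. A lower share of leukocytes as the whole cause stays open. Marker RNA in other cells, or an uneven loss, would also give unequal falls. Library scaling is excluded, as 1 factor per library moves all genes alike. The list median minus the median of all tested genes was -1.74 (SE of the median 0.0994, log2) in the comparison where it lay closest to 0, eWAT Cont. A change in the type of leukocytes, or a direct effect of the knockdown within them, may lie behind the falls and was not tested.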

How the results depend on the processing

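Tests added after the data were seen are the summed libraries, the block across depots, and the fits without iWAT aKO siNS replicate 2 for contrasts that do not hold it. Other settings were planned. In eWAT and iWAT the planned fit of all libraries gave 3013 and 2243 genes for genotype with siNS, 3958 and 3597 for knockdown in Cont and 5274 and 4624 in aKO. It gave 1592 and 1483 for genotype with siCEBPb, 938 and 519 for the interactions and 178 for depot. DESeq2 size factors, the stricter filter and the DESeq2 Wald test kept the 12 gene counts within 1.5 times. With the replicate number within each depot as a replicate block, counts were 2739 and 2032 for genotype with siNS, 3705 and 3371 for knockdown in Cont, 4990 and 4347 in aKO, 1452 and 1326 for genotype with siCEBPb, 778 and 444 for the interactions and 0 for depot by genotype (edgeR QL). The planned block could not be estimated for the depot comparison and was not run there, where the block across depots gave 143 genes. List calls went from 152 to 151 with the block over 11 contrasts. With a block within depot and genotype the interactions gave 518 and 309, and the cause was not tested. Across depots 21 of 22 libraries correlated best with their own number.

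Requiring also at least a doubling or halving gave 523 and 504 genes for genotype with siNS, 1010 and 1002 for knockdown in Cont, 1471 and 1468 in aKO, 496 and 501 for genotype with siCEBPb, 260 and 184 for the interactions and 56 for depot, by the construction of that threshold. With the groups of a contrast alone the counts were 718 for iWAT genotype with siNS, 2231 for iWAT knockdown in aKO, 1447 and 303 for the interactions and 710 for depot. With voom they were 5938 for eWAT knockdown in Cont, 2568 for iWAT genotype with siCEBPb, 2059 and 1235 for the interactions and 852 for depot. Summed eWAT and iWAT libraries gave 4641 genes for genotype with siNS, 5656 for knockdown in Cont and 7215 in aKO, 2959 for genotype with siCEBPb and 2247 for the interaction. Without a filter 921 genes passed the iWAT interaction, 542 the depot and 18 the depot by genotype test. The correlations across genes were then 0.619 for iWAT genotype with both siRNAs, 0.839 and 0.848 for knockdown in both genotypes and 0.890 for genotype in both depots. The cause was not tested.

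Leaving out 1 library at a time gave 2087 to 3857 and 1436 to 2752 genes for genotype with siNS, 3104 to 4753 and 2822 to 4360 for knockdown in Cont, 4294 to 6099 and 3611 to 5199 in aKO and 1097 to 2161 and 942 to 1972 for genotype with siCEBPb. It gave 434 to 1677 and 291 to 939 for the interactions, 23 to 1123 for depot and 0 to 0 for depot by genotype (edgeR QL, 415 at an unadjusted p under 0.05 with all libraries). In 11 contrasts the highest count was the one without iWAT aKO siNS replicate 2. Correlations ranged from 0.589 to 0.685 and 0.638 to 0.718 for genotype with both siRNAs, 0.853 to 0.890 and 0.866 to 0.895 for knockdown and 0.893 to 0.940 for genotype in both depots. List calls numbered 145 to 179.

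Of 157 list calls, 40 held with an estimated correlation, 106 with fry, 156 with no filter and 157 with DESeq2 size factors. Over libraries left out, 1056 of 1140 list values kept their call, 79 lost it, 4 turned into calls of the other direction and 1 changed direction and was no longer called. These last 5 arose without iWAT aKO siNS replicate 2 and had a camera adjusted p of 1.05e-04 (respiration, iWAT genotype with siNS), 5.08e-04 (respiration, iWAT knockdown in aKO), 0.00295 (respiration, iWAT interaction), 9.28e-04 (ribosomal proteins, iWAT knockdown in aKO) and 0.376 (ribosomal proteins, iWAT interaction). With libraries left out in turn, these 5 values ranged over 2.75e-06 to 0.00939, 2.29e-05 to 0.0125, 1.75e-07 to 0.00295, 1.14e-07 to 0.00139 and 1.14e-11 to 0.376 in the same order. Values of named genes kept their call in 1797 of 1836 cases with libraries left out, and 0 reversed. The cause of the effect of iWAT aKO siNS replicate 2 was not tested.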

Other observations

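The tests on exon length were chosen after the result was seen, and the counts over splits were planned.

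Secretory and hormone genes not described above also moved. Genes of the endoplasmic reticulum stress response fell with siCEBPb in Cont in 14 of 20 cases in eWAT and 12 in iWAT (15 and 14 adjusted over the list alone), with Sdf2l1 at -0.82 ± 0.098 and -1.17 ± 0.11 and the protein disulfide isomerase Pdia6 at -0.51 ± 0.077 and -0.53 ± 0.077. Camera on stress response genes gave adjusted p = 1.16e-05, 0.127 with an estimated correlation in eWAT and adjusted p = 2.66e-05, 0.144 with an estimated correlation in iWAT. Secreted adipokine genes fell in 8 and 7 of 16 cases (9 in each changed adjusted over the list alone), with Apln, which encodes apelin, at -2.31 ± 0.15 and -2.19 ± 0.16 and Angptl2 at -0.84 ± 0.082 and -0.83 ± 0.083. Camera on adipokine genes gave adjusted p = 1.48e-04, 0.186 with an estimated correlation in eWAT and adjusted p = 3.52e-04, 0.214 with an estimated correlation in iWAT. Leukocyte markers fell beside them, with a median of -1.72 in eWAT and -1.89 in iWAT.

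In aKO cultures with siNS, TGF-beta and Wnt genes that act against adipocyte differentiation changed both ways. In eWAT 10 of 23 rose and 6 fell, as in iWAT, and 18 and 16 changed adjusted over the list alone. Sfrp2, a secreted Wnt regulator, rose (1.40 ± 0.15 and 1.45 ± 0.15), and Inhba, a subunit of activin, fell (-1.20 ± 0.12 and -1.09 ± 0.13). Camera called the list upward (adjusted p = 0.0140, 0.284 with an estimated correlation in eWAT; adjusted p = 0.0292, 0.380 with an estimated correlation in iWAT), but in iWAT not with libraries left out (camera adjusted p = 0.0940 without iWAT Cont siNS replicate 2, 0.132 without iWAT aKO siNS replicate 1 and 0.163 without iWAT aKO siNS replicate 3). White fat genes were called upward in eWAT, where 10 of 20 rose and 2 fell (12 adjusted over the list alone; median 0.44, camera adjusted p = 0.00657, adjusted p = 0.367 with an estimated correlation), with angiotensinogen, Agt, at 0.90 ± 0.15.

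For comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each of the 9. For genotype with siNS the real splits gave 3013 in eWAT and 2243 in iWAT, with 0 and 325 as the highest others (edgeR QL). For knockdown in Cont they gave 3958 and 3597, with 0 and 0, and in aKO 5274 and 4624, with 0 and 1197. For genotype with siCEBPb they gave 1592 and 1483, with 0 and 0, and for depot 178, with 0. For the depot by genotype interaction, 33 of 33 splits gave at least its 0 genes (edgeR QL, 415 at an unadjusted p under 0.05, 0 by DESeq2 and voom), and 1 split gave 673 by exchanging replicates 1 and 3 of Cont and aKO siNS in eWAT. That split turns the genotype difference in eWAT into an interaction, so the splits decide nothing about chance here.

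A hypothesis was that pseudogenes and mitochondrial genes were higher in iWAT than eWAT libraries of Cont siNS through a library difference that goes with transcript length. The Spearman correlation across 14961 genes of the depot difference with exon length was, without iWAT aKO siNS replicate 2, -0.135 in Cont siNS, 0.0869 in Cont siCEBPb, 0.0561 in aKO siNS and 0.0155 in aKO siCEBPb. Genes are not independent and the test was chosen late, but only Cont siNS was negative, which argues against a difference in all 4 conditions. In Cont siNS alone it stays open, as -0.135 lies between bounds of -0.2 and -0.1. It would leave the mitochondrial genes of other conditions unexplained, as they held 1.199% to 1.69% of gene counts in all iWAT and 0.484% to 1.12% in all eWAT libraries, without that library.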
